A study of Saccharomyces cerevisiae with 11 samples.

How the data were processed

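The series measured transcript levels in 11 libraries of Saccharomyces cerevisiae: GD, SD and RD strains with 3 libraries each, a control and ControlSYN3. Per the labels' protocols, cells were frozen on dry ice and ground under liquid nitrogen, RNA was taken up in Trizol, and libraries were made with oligo-dT beads. Such libraries hold mainly polyadenylated transcripts. Whether the libraries keep strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart.

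The deposited values are FPKM computed by the authors, per the file headers, in 2 tables. The submitters' processing notes name RSEM, Bowtie2 and BWA and the genome build R64, with no versions, roles or order. How reads of recoded and wild-type gene copies were assigned is not given in the sources used here beyond the use of sequence tags. FPKM are scaled within a library by the authors, so a few abundant genes can shift all others, and they hold no depth. Whether low values resolve into whole fragments was checked in each library, over a grid of fragment lengths and library sizes. The mean distance to a whole number at the best grid point was 0.168 to 0.194, against medians of 0.187 to 0.196 over 20 shuffles of the gene lengths, and in ControlSYN3 alone (0.1678) it lay below all 20 shuffles, the lowest of which gave 0.1686, so whole fragments were not recovered and the depth is unknown. Intervals from counts are therefore not given.

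Rows were matched by gene number to the R64 reference annotation, which gave symbols and reference coordinates. Of 5936 rows in the table of GD, SD and control, 5774 matched; 159 carry short numbers and 3 long numbers without a match. Of 5931 rows in the other table, 5770 matched. The short-number rows were tested but are not named. Columns were given to samples by their names; 3 columns headed MD1, MD5 and MD6 were given to RD1, RD5 and RD6 by number, which is an inference, as the letters differ. No column lacked a sample.

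The plan assumed counts, with a test on log2 values for FPKM as the fallback. The tables hold FPKM, so the planned count tests, their normalization alternative and the joint fit of both tables were not run. Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trend and robust empirical Bayes estimates, one model per table with a mean per group, and Benjamini-Hochberg adjustment at 0.05 over all genes of the table. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Genes with a mean of at least 1 FPKM over the table were tested, 5899 and 5895 genes; this minimum was chosen after the files were seen to hold FPKM. The fits left 4 residual degrees of freedom for GD, SD and control and 2 for RD and ControlSYN3. The lone wild-type libraries were assumed to vary like the strains. Gene lists (48, of which 47 had at least 3 measured members) and the 32 nuclear chromosome arms were tested with limma's camera. The preset correlation was 0.01, and an estimated correlation and limma's fry were the alternatives. With an estimated correlation, camera also takes its p-values on the residual degrees of freedom of the fit. With a preset one its degrees of freedom follow the number of genes. A rise in p with the estimated correlation can therefore come from either. Camera sets a list against all other genes, while fry asks whether its genes changed at all. A shift of all genes can therefore move fry. Adjusted p-values of camera are over the lists or arms of a comparison.

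On simulated data, with the real means and spread and 200 changed genes, 4-fold changes were recovered in 92% of cases for GD against control (2-fold in 26%), 92% for SD against control (34%), 96% for GD against SD (75%) and 49% for RD against ControlSYN3 (2%). False calls numbered 8, 6, 9 and 1, and no call had the wrong sign. The changed genes were drawn only from those above a minimum mean level. The simulated wild-type libraries were given the spread of the strains, with independent noise and no shift of a whole library. These figures therefore do not cover a wild-type library that varies more or is shifted.

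Before the data were examined, the gene lists, the comparisons, the alternatives and the rule for named genes were fixed. The rule took the 8 highest and 8 lowest called genes with a mean of at least 10 (planned in CPM, applied as FPKM) and the same sign in every strain; the 3 members with the lowest p of each list past camera; all essential genes of chromosome III; rows marked as synthetic copies, of which there were none; called marker genes; and the 2 lowest-p genes of each arm past camera. The lists past camera were too many to describe, and the text keeps to part of them, a choice made afterwards for length. Named genes are given with their mean and SD over strains where values are above 0.

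The alternatives were no minimum, a minimum of 10 FPKM, a pseudocount of 0.1, a 2-fold threshold, fits of only the groups compared, a replicate block and leaving out each strain library; median-of-ratios scaling, rescaling of each library to the same total and the gene lists without RD1 were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.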

Results

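Polyadenylated RNA of 11 samples of budding yeast (Saccharomyces cerevisiae) was sequenced, and gene expression was deposited as FPKM (fragments per kilobase of gene, scaled to the mapped fragments of a library). The labels name 3 strain groups, GD, SD and RD, with 3 libraries each, and 2 wild-type libraries called control and ControlSYN3. They do not spell out the abbreviations. The series concerns essential genes placed in clusters, and short recoded sequence tags were used to tell transcripts of synthetic genes from those of wild-type genes. One table held control, GD and SD (5936 rows) and the other held ControlSYN3 and 3 columns headed MD (5931 rows). The MD columns 1, 5 and 6 were taken for RD1, RD5 and RD6 by their numbers, which is an inference, since no label holds the letters MD. All tests were made within a table. The depth of the libraries is unknown, because FPKM carry no read counts. Each library of a group is a separately numbered strain sample with one genotype label, and the labels do not say whether these were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical, and each single wild-type library was assumed to vary like the strains.

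SD libraries resembled each other more than GD libraries did, and RD1 stood apart from RD5 and RD6. The Spearman correlation across genes, which are not independent replicates, was 0.98 to 0.992 between SD libraries and 0.918 to 0.976 between GD libraries. RD5 and RD6 correlated at 0.993 and differed by more than 2-fold in 6 of 5569 rows. RD1 correlated at 0.906 with RD5 and at 0.939 with ControlSYN3. CCW12, a cell wall mannoprotein gene, was the most abundant transcript in GD, RD and ControlSYN3. SPO24 was the most abundant in SD, at 17894 to 19098 FPKM, and FIT3, a cell wall protein gene of iron uptake, led in the control at 20316 FPKM. RD1 also differed in its mating-type genes. The pheromone gene MFA2, which a-type cells express, stood at 2559 FPKM in RD1 and at 3.47 to 7.48 FPKM in ControlSYN3, RD5 and RD6. The alpha-type pheromone gene MF(ALPHA)1 stood at 27.4 FPKM in RD1 and at 5895 to 6637 FPKM in those 3 libraries. LYS2, of lysine synthesis, was at 174 FPKM in RD1, at 0.02 FPKM in RD5 and listed at 0 in RD6 and ControlSYN3.

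The first question was how the essential genes of chromosome III were expressed, as the title is about clustered essential genes. A list of 15 such genes was fixed before the data were examined, and 13 of them had a row with a reference identifier. The median of these 13 genes was lower in the control and GD than in SD, and lower in ControlSYN3 than in RD. It was 36.3 FPKM in the control and 39.2, 38.7 and 30.7 FPKM in GD1, GD2 and GD3, and 222, 189 and 224 FPKM in SD1, SD2 and SD3. In the other table it was 8.86 FPKM in ControlSYN3 and 74.9, 129 and 123 FPKM in RD1, RD5 and RD6. All 13 genes were higher than the wild-type library of their table in every SD and every RD library. Single genes ranged widely, and RRP7 stood at 262 FPKM in the control and at 295 to 312 FPKM in SD. Among all rows of a library, the median percentile of the 13 genes was 21.8 in the control, 30.5 to 34.1 in GD and 81.9 to 84.2 in SD. It was 5.38 in ControlSYN3 and 60.4 to 76.8 in RD. Whether a row holds the whole expression of its gene is not known, so a higher value need not mean induction. No row was marked in the tables as a synthetic or a wild-type copy, so values of the copies could not be given apart.

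**Figure D1:**
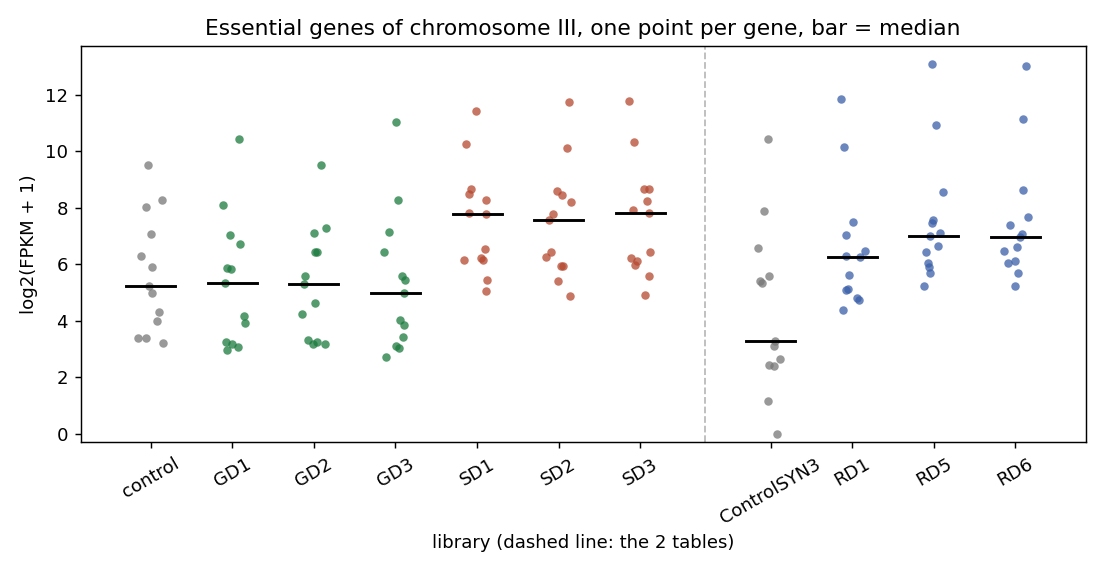
FPKM of the 13 measured essential genes of chromosome III in each of the 11 libraries, as log2(FPKM + 1) on the vertical axis, with one point per gene and a bar at the median. The SD and RD libraries lie above the wild-type library of their own table, with medians of 189 to 224 FPKM in SD against 36.3 FPKM in the control, while GD lies near the control.

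SPB1, a ribosome biogenesis methyltransferase gene (chromosome III, 31449 to 33974 in the R64 reference), showed the highest SD to control ratio among these genes. It reached 87.9 ± 3.58 FPKM in SD (SD, n = 3) against 7.64 ± 1.09 FPKM in GD (SD, n = 3) and 8.41 FPKM in the control. Its log2 fold change was 3.24 ± 0.20 (SE) for SD against the control (limma adjusted p = 0.000613) and -3.37 ± 0.14 (SE) for GD against SD (limma adjusted p = 5.63e-05). PBN1, of glycosylphosphatidylinositol anchor synthesis (34143 to 35393), reached 373 ± 32.3 FPKM in SD and 48.5 ± 6.73 FPKM in GD (SD, n = 3 each). NFS1, the cysteine desulfurase of iron-sulfur cluster assembly (92777 to 94270), reached 219 ± 27.9 FPKM in SD and 36.2 ± 4.77 FPKM in GD (SD, n = 3 each). CTR86 (218376 to 220067) reached 68.2 ± 7.57 FPKM in SD and 7.22 ± 1.42 FPKM in GD (SD, n = 3 each), and RRP43, an exosome subunit gene (191834 to 193018), reached 400.2 ± 11.6 FPKM in SD and 63.8 ± 20.7 FPKM in GD (SD, n = 3 each). These positions are those of the reference genome, and the strains may carry the genes elsewhere.

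In SD against the control, 12 of the 13 genes were higher: KRR1, SPB1, PBN1, PDI1, NFS1, PGS1, PGK1, RRP43, CTR86, PWP2, RSA4 and CDC39. The exception was RRP7, at 304 ± 8.56 FPKM in SD (SD, n = 3) and 262 FPKM in the control (limma adjusted p = 0.407). The median log2 fold change was 2.13, with 12 genes also called when adjusted over the list alone (camera adjusted p = 2.51e-11, and adjusted p = 0.168 with an estimated correlation). The call of KRR1 was lost without SD1 (limma adjusted p = 0.0705), SD2 (0.0566) or SD3 (0.075), and that of PGK1 without SD3 (0.0514). Between GD and SD, all 13 genes were lower in GD, by a median of -2.28, and all 13 were called when adjusted over the list alone (camera adjusted p = 5.96e-10, and adjusted p = 0.224 with an estimated correlation). PGK1, of glycolysis, had the weakest of these calls (log2 fold change -1.32 ± 0.38, SE; limma adjusted p = 0.0285) and was not called with median-of-ratios scaling (0.0534), nor without GD1 (0.0735), SD1 (0.0601), SD2 (0.0771) or SD3 (0.0997). GD differed little from the control over this list. PGS1 (log2 fold change -1.12 ± 0.18, SE) and RRP7 (-0.94 ± 0.20, SE) were lower and 11 of the 13 were not called, with 2 lower when adjusted over the list alone. Both calls were lost in the fit of only GD and the control (limma adjusted p = 0.0916 for PGS1 and 0.099 for RRP7). The list median of -0.37 lay 0.07 above the median of all genes (camera adjusted p = 0.882, and adjusted p = 0.986 with an estimated correlation), and median-of-ratios scaling, with which RRP7 was not called, turned it to 0.05. Fry, in place of camera and without that scaling, called the list lower in GD (adjusted p = 0.0308). Fry does not set a list against other genes, and the median of all genes was itself at -0.44. This call therefore does not set the list apart from other genes.

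The remaining matched rows of chromosome III, POL4 and YCR051W, were chosen for description after their values were seen. POL4, a DNA polymerase gene, stood at 26.7 ± 1.10 FPKM in SD and 21.8 ± 2.79 FPKM in GD (SD, n = 3 each), with 42.5 FPKM in the control. It was lower than the control in SD (log2 fold change -0.65 ± 0.19, SE; limma adjusted p = 0.0294) and in GD (limma adjusted p = 0.0124), and not called between GD and SD (limma adjusted p = 0.128). YCR051W stood at 109 ± 10.2 FPKM in SD and 70.7 ± 19.4 FPKM in GD (SD, n = 3 each), with 103 FPKM in the control, and was lower in GD than in SD (log2 fold change -0.65 ± 0.21, SE; limma adjusted p = 0.0399).

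Compared with the control, 26 of 49 genes of amino acid biosynthesis were higher in GD strains, and 23 of 33 proteasome genes and 12 of 25 DNA damage response genes were lower, though none and 4 of them with median-of-ratios scaling. Amino acid biosynthesis genes had the lowest camera p of the lists: 26 of 49 rose, 2 fell and 21 were not called, with 30 higher and 2 lower when adjusted over the list alone (camera adjusted p = 1.53e-22, and adjusted p = 0.986 with an estimated correlation). ARG1, of arginine synthesis, reached 2582 ± 1480 FPKM in GD (SD, n = 3) and 48.9 FPKM in the control (log2 fold change 5.52 ± 0.62, SE, limma adjusted p = 0.00336). In ControlSYN3, the other wild-type library, it stood at 4915 FPKM, though the 2 were not compared by a test. A state of the single control library cannot be told apart from a change in GD or SD. ARO4, the first enzyme gene of aromatic amino acid synthesis, reached 605 ± 69.9 FPKM (SD, n = 3) against 66.8 FPKM in the control, and ILV2, of branched-chain amino acid synthesis, 566 ± 143 FPKM (SD, n = 3) against 73.9 FPKM.

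In all, 1895 of 5899 genes were called in GD against the control, 294 higher and 1601 lower. The median of all genes was shifted by -0.44 on the log2 scale, and with median-of-ratios scaling, chosen after this shift was seen, 550 genes were higher and 530 lower. Medians of lists against the control are therefore given less the median of all genes, and that of amino acid biosynthesis was 2.19 in GD. The 8 highest genes by the naming rule were ZRT1, ARG3, ARG1, HIS3, SNZ1, BIO3, VHT1 and LEU1, with log2 fold changes of 3.50 to 5.67. ZRT1, the high-affinity zinc transporter gene, reached 2629 ± 802 FPKM in GD (SD, n = 3) against 49.2 FPKM in the control (limma adjusted p = 0.00211). BIO3 and VHT1 act in biotin synthesis and uptake. The 8 lowest were FIT3, LSO1, a numbered row without reference match, CPP2, CYC7, CAR1, SPR28 and YHR022C-A. FIT3 stood at 226 ± 132 FPKM in GD (SD, n = 3) against 20316 FPKM in the control, with a log2 fold change of -6.64 ± 0.82 (SE; limma adjusted p = 0.00406). CAR1, the arginase gene, stood at 36.3 ± 16 FPKM (SD, n = 3) against 652 FPKM, and CYC7, a cytochrome c isoform gene, at 32.04 ± 12.5 FPKM (SD, n = 3) against 578 FPKM.

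Large-subunit ribosomal protein genes lay 0.98 above the median of all genes in GD against the control, with 6 of 81 higher, none lower and 75 not called, and with 3 higher when adjusted over the list alone (camera adjusted p = 3.77e-13, and adjusted p = 0.986 with an estimated correlation). Small-subunit genes lay 0.89 above it, with 4 of 56 higher, none lower and 52 not called, and none when adjusted over the list alone (camera adjusted p = 3.35e-10, and adjusted p = 0.986 with an estimated correlation). Without taking off the median of all genes, the large-subunit medians were 0.329, 0.152 and 1.02 in GD1, GD2 and GD3. The small-subunit medians were 0.264, 0.165 and 0.991, so the shift was largest in GD3. Neither list was called by fry (adjusted p = 0.518 for both), which tests for a change from the control and not against other genes. RPL3 stood at 1642 ± 554 FPKM in GD (SD, n = 3) and 335 FPKM in the control. Glycolysis genes lay 1.16 above the median of all genes, with 5 of 20 higher, none lower and 15 not called, and none when adjusted over the list alone (camera adjusted p = 3.44e-05, and adjusted p = 0.986 with an estimated correlation). Their medians, without taking off that of all genes, were 0.744, 0.107 and 1.1 in GD1, GD2 and GD3. The list was not called by fry (adjusted p = 0.354). PDC1, pyruvate decarboxylase, stood at 4709 ± 969 FPKM (SD, n = 3) against 1642 FPKM. Cell wall genes lay 0.63 above the median of all genes, and 12 of 41 were higher, 2 lower and 27 not called, with 13 higher and 2 lower when adjusted over the list alone (camera adjusted p = 5.88e-07, and adjusted p = 0.793 with an estimated correlation). Proteasome genes had a median of -0.43 less that of all genes, with 23 of 33 lower and 10 not called, and 27 lower when adjusted over the list alone (camera adjusted p = 9.02e-05, and adjusted p = 0.986 with an estimated correlation). With median-of-ratios scaling none of them was called. DNA damage response genes had a median of -0.47 less that of all genes, and 12 of 25 were lower and 13 not called, with 16 lower when adjusted over the list alone (camera adjusted p = 0.012, and adjusted p = 0.986 with an estimated correlation), and 4 lower and 1 higher with that scaling. HUG1, a ribonucleotide reductase inhibitor gene, stood at 9.27 ± 4.41 FPKM (SD, n = 3) against 93.7 FPKM. By fry the adjusted p was 0.0591 for cell wall genes, 0.0308 for proteasome genes and 0.0159 for DNA damage response genes. As fry does not set a list against other genes, the shift of all genes enters these values.

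Several marker genes of strain construction differed. HIS3, of histidine synthesis, stood at 4975, 15693 and 4231 FPKM in GD1, GD2 and GD3 and at 4256 to 4942 FPKM in SD, against 209 FPKM in the control. URA3, of uracil synthesis, stood at 1139 to 1352 FPKM in GD and 1296 FPKM in the control, but at 108 ± 8.05 FPKM in SD (SD, n = 3; limma adjusted p = 0.000613 for SD against the control). LYP1, the lysine permease gene, was higher in GD (158 ± 53.0 FPKM) and SD (196 ± 16.4 FPKM; SD, n = 3 each) than in the control (43.9 FPKM). MET17, of methionine synthesis, was higher in SD, at 1160 ± 269 FPKM (SD, n = 3), than in the control, at 147 FPKM. In ControlSYN3 HIS3 stood at 1116 FPKM, URA3 at 377 FPKM, LYP1 at 221 FPKM and MET17 at 775 FPKM. The listed values of the wild-type libraries thus differed in these genes as well. These libraries come from different tables and were not compared by a test.

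The chromosome arm test singled out the right arm of chromosome II in GD against the control, where 301 genes lay 0.30 above the median of all genes (camera adjusted p = 0.00805, and adjusted p = 0.979 with an estimated correlation). The arm lay 0.34 above it in GD1, 0.05 in GD2 and 0.54 in GD3. ARO4 (716882 to 717994) and ADH5, an alcohol dehydrogenase gene (533762 to 534817), had the lowest p on this arm. In SD against the control and in GD against SD, the arms past the test were both arms of chromosome III. Their 7 and 8 matched rows are mostly the essential genes above, with a camera adjusted p of 6.62e-06 and 0.000301 for SD against the control (adjusted p = 0.372 and 0.551 with an estimated correlation) and of 8.54e-06 and 0.000277 for GD against SD (adjusted p = 0.384 and 0.544 with an estimated correlation).

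**Figure D2:**
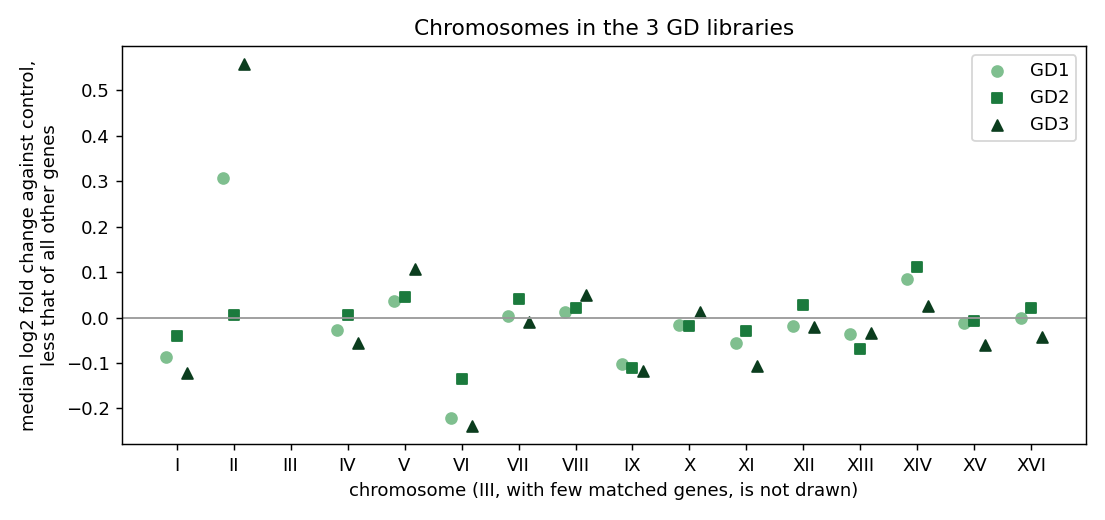
Median log2 fold change against the control of the genes of each chromosome, less that of all other genes, with one symbol per GD library. Chromosome II lay at 0.31 in GD1, 0.01 in GD2 and 0.56 in GD3.

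The count for GD against the control depended on which libraries were in the fit: it was 1228 without SD1, 1176 without SD3 and 233 when the fit held only GD and the control. The SD libraries enter the spread used in this test, and they differed less from each other than the GD libraries did. Calls of GD against the control therefore rest partly on that smaller spread. The call of YHR022C-A was lost without GD1, GD3 or SD3 and with median-of-ratios scaling, and that of PDC1 without SD3.

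In SD strains, most of the listed stress-induced genes were higher than in the control and most of the listed cell cycle genes lower. Whether a difference in growth state between the libraries accounts for these lists was not tested. Of 45 genes induced in the environmental stress response, 26 rose, none fell and 19 were not called, with 27 higher when adjusted over the list alone and 30 higher with median-of-ratios scaling (camera adjusted p = 1.39e-14, and adjusted p = 0.703 with an estimated correlation). TKL2, a transketolase gene, reached 213 ± 47.0 FPKM in SD (SD, n = 3) against 23.7 FPKM in the control (log2 fold change 3.09 ± 0.32, SE; limma adjusted p = 0.00101), and GAD1, glutamate decarboxylase, 659 ± 29.7 FPKM (SD, n = 3) against 188 FPKM. Of 19 genes of the G1/S transition, 18 fell and 1 was not called, with 18 lower when adjusted over the list alone and 15 lower and 1 higher with that scaling (camera adjusted p = 5.83e-05, and adjusted p = 0.828 with an estimated correlation). MCD1, a cohesin subunit gene, stood at 5.93 ± 1.90 FPKM (SD, n = 3) against 108 FPKM, and the G1 cyclin gene PCL1 at 26.3 ± 5.92 FPKM (SD, n = 3) against 199 FPKM.

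Overall counts for SD against the control were 2468 of 5899 genes, 616 higher and 1852 lower. The median of all genes was shifted by -0.37, and median-of-ratios scaling gave 1103 higher and 1032 lower. Less the median of all genes, the list medians were 1.82 for stress-induced genes and -1.35 for G1/S genes. The 8 highest were SNZ1, HXT6, ARG3, YOR186W, a numbered row without reference match, SPG4, ZRT1 and ARG1, with log2 fold changes of 4.83 to 6.003. SNZ1, of vitamin B6 synthesis, reached 2276 ± 607 FPKM (SD, n = 3) against 33.6 FPKM, and SPG4, a stationary phase gene, 2177 ± 401 FPKM (SD, n = 3) against 59.5 FPKM. HXT6 and HXT7 are nearly identical hexose transporter genes that share reads, so their separate values are uncertain. The 8 lowest were FIT3, LSO1, CPP2, URA1, CAR1, UTR2, MCD1 and POL30, with log2 fold changes of -6.48 to -3.99. URA1, of pyrimidine synthesis, stood at 124 ± 9.63 FPKM (SD, n = 3) against 2471 FPKM, and POL30, the replication clamp gene, at 9.90 ± 3.57 FPKM (SD, n = 3) against 166 FPKM.

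Part of the genes in lists of energy metabolism, and part of those of amino acid and methionine synthesis, were higher in SD than in the control. Less the median of all genes, the medians were 0.88 for the respiratory chain, 1.16 for the tricarboxylic acid cycle, 1.49 for gluconeogenesis and the glyoxylate cycle, 2 for amino acid biosynthesis and 1.76 for methionine and sulfur genes. Of 34 respiratory chain genes, 7 were higher and 27 not called, with 7 higher when adjusted over the list alone and 11 with median-of-ratios scaling (camera adjusted p = 2.84e-07, and adjusted p = 0.703 with an estimated correlation). NDI1, the internal NADH dehydrogenase gene, reached 319 ± 27.9 FPKM (SD, n = 3) against 108 FPKM. Of 16 tricarboxylic acid cycle genes, 5 were higher and 11 not called, with 4 higher when adjusted over the list alone and 10 with that scaling (camera adjusted p = 5.73e-06, and adjusted p = 0.74 with an estimated correlation). SDH2, a succinate dehydrogenase subunit gene, reached 821 ± 29.2 FPKM (SD, n = 3) against 238 FPKM. Of 16 gluconeogenesis and glyoxylate cycle genes, 7 were higher, 2 lower and 7 not called, with 7 and 2 when adjusted over the list alone and 8 and 1 with that scaling (camera adjusted p = 0.00118, and adjusted p = 0.703 with an estimated correlation). Of amino acid biosynthesis genes, 27 of 49 rose, 3 fell and 19 were not called, with 30 higher and 4 lower when adjusted over the list alone and 33 and 2 with that scaling (camera adjusted p = 3.2e-12, and adjusted p = 0.703 with an estimated correlation). Of 29 methionine and sulfur genes, 10 were higher, none lower and 19 not called, with 9 higher when adjusted over the list alone and 14 with that scaling (camera adjusted p = 2.66e-07, and adjusted p = 0.74 with an estimated correlation). MET6, methionine synthase, reached 539.5 ± 64 FPKM (SD, n = 3) against 53.2 FPKM.

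Most of the listed G2/M, histone and ribosome biogenesis genes were lower in SD than in the control. Less the median of all genes, the medians were -1.01 for G2/M genes, -0.95 for histone genes and -0.46 for ribosome biogenesis genes. Of 16 genes of the G2/M transition, 12 fell and 4 were not called, with 12 lower when adjusted over the list alone and 10 lower and 1 higher with that scaling (camera adjusted p = 0.0104, and adjusted p = 0.703 with an estimated correlation). The mitotic cyclin gene CLB2 stood at 9.99 ± 0.855 FPKM (SD, n = 3) against 64.4 FPKM. Of 11 histone genes, 8 were lower and 3 not called, with 9 lower when adjusted over the list alone (camera adjusted p = 0.0252, and adjusted p = 0.74 with an estimated correlation), and HTB1, a histone H2B gene, stood at 1290 ± 87.6 FPKM (SD, n = 3) against 5264 FPKM. With median-of-ratios scaling 4 histone genes were lower and 1 higher. Of 61 ribosome biogenesis genes, 36 were lower, 6 higher and 19 not called, with 37 lower and 6 higher when adjusted over the list alone and 23 lower and 8 higher with that scaling (camera adjusted p = 0.0398, and adjusted p = 0.955 with an estimated correlation). NOP56, of the small nucleolar ribonucleoprotein, stood at 115 ± 12 FPKM (SD, n = 3) against 826 FPKM, while SPB1 and PWP2 of chromosome III were among the higher ones.

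GD and SD shared many calls against the control, though both comparisons use the same library. In the same direction, 185 genes were higher and 1032 lower in both, and 61 moved in opposite directions. With median-of-ratios scaling, chosen after seeing the data, 377 were higher and 313 lower in both and 30 moved in opposite directions, so most of the shared lower calls depended on the shift of all genes. Independent lists of these sizes would share 30.7 higher and 502.6 lower genes, and unchanged groups set against the control gave 0 shared calls in 50 simulations. With no true change the adjusted threshold leaves few calls to share, so this 0 does not measure how many shared calls come from the common control. The fold changes correlated at 0.584 across genes against 0.748 in the simulation, with a covariance of 0.54 against 0.0867. The sign was the same in 74.9% of genes against 77% in the simulation. Of these measures only the covariance lay above the simulation. Part of that excess, and of the shared calls, may come from the shared control, which cannot be split. FIT3, LSO1, CPP2 and CAR1 were among the 8 lowest and ZRT1, ARG1, ARG3 and SNZ1 among the 8 highest in both comparisons.

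GD set directly against SD, with 3 libraries on either side, had lower levels of most listed stress-induced genes and higher levels of most listed ribosomal protein genes. Of 45 stress-induced genes, 42 were lower in GD and 3 not called, with 44 lower when adjusted over the list alone (camera adjusted p = 4.82e-18, and adjusted p = 0.37 with an estimated correlation). RTN2 stood at 31.2 ± 2.64 FPKM in GD and 360.2 ± 64.5 FPKM in SD (SD, n = 3 each; log2 fold change -3.48 ± 0.18, SE; limma adjusted p = 6.87e-05). Large-subunit ribosomal protein genes were higher in GD in 76 of 81 cases, with 5 not called and 78 higher when adjusted over the list alone (camera adjusted p = 8.33e-18), and small-subunit genes in 55 of 56, with 1 not called and 55 when adjusted over the list alone (camera adjusted p = 1.7e-15). For both the adjusted p was 0.62 with an estimated correlation. As for SD against the control, growth state was not tested as an account of these lists. RPL15A, which like many ribosomal protein genes has a near-identical copy that can share its reads, stood at 2365 ± 663 FPKM in GD and 838 ± 206 FPKM in SD (SD, n = 3 each).

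In this comparison 2408 of 5899 genes were called, 1205 higher and 1203 lower in GD, and the median of all genes was shifted by -0.04. The groups did not overlap in 3325 genes (56.4%), where chance gives 10% for 3 against 3. The 8 highest in GD were URA3, MF(ALPHA)2, ENO2, ADH4, UTR2, TOS6, VEL1 and POL30. ENO2, the enolase gene, stood at 3795 ± 1700 FPKM in GD and 378 ± 26.1 FPKM in SD (SD, n = 3 each; log2 fold change 3.23 ± 0.34, SE; limma adjusted p = 0.000646). The 8 lowest included 3 numbered rows without reference match, with SPG4, SPG1, HXT6, SPS100 and YOR186W. SPG1 stood at 4.24 ± 3.02 FPKM in GD and 171 ± 47.3 FPKM in SD (SD, n = 3 each).

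Lists that divided GD from SD further included the respiratory chain, with 26 of 34 genes lower in GD and 8 not called, and 29 lower when adjusted over the list alone (camera adjusted p = 3.23e-11, and adjusted p = 0.419 with an estimated correlation). NDE1, an external NADH dehydrogenase gene, stood at 71.5 ± 10.7 FPKM in GD and 280.4 ± 22.4 FPKM in SD (SD, n = 3 each). Heat shock and chaperone genes were lower in GD in 20 of 29 cases, with 2 higher and 7 not called, and 21 and 2 when adjusted over the list alone (camera adjusted p = 1.81e-06, and adjusted p = 0.46 with an estimated correlation). HSP26, a small heat shock protein gene, stood at 518 ± 172 FPKM in GD and 8556 ± 2410 FPKM in SD (SD, n = 3 each). Of 19 G1/S genes 16 were higher in GD and 3 not called, with 16 when adjusted over the list alone (camera adjusted p = 3.79e-07, and adjusted p = 0.62 with an estimated correlation). The G1 cyclin gene CLN2 stood at 130 ± 19.6 FPKM in GD and 23.9 ± 3.48 FPKM in SD (SD, n = 3 each). Of 16 G2/M genes 14 were higher, 1 lower and 1 not called, with 14 and 1 when adjusted over the list alone (camera adjusted p = 4.43e-07, and adjusted p = 0.37 with an estimated correlation). Ribosome biogenesis genes were higher in GD in 39 of 61 cases, with 5 lower and 17 not called, and 45 and 5 when adjusted over the list alone (camera adjusted p = 4.39e-07, and adjusted p = 0.62 with an estimated correlation). The 5 lower ones were SPB1, PWP2, RSA4, KRR1 and RRP7, essential genes of chromosome III. The count of called genes was 1570 without SD1 and 1263 without SD3.

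**Figure D3:**
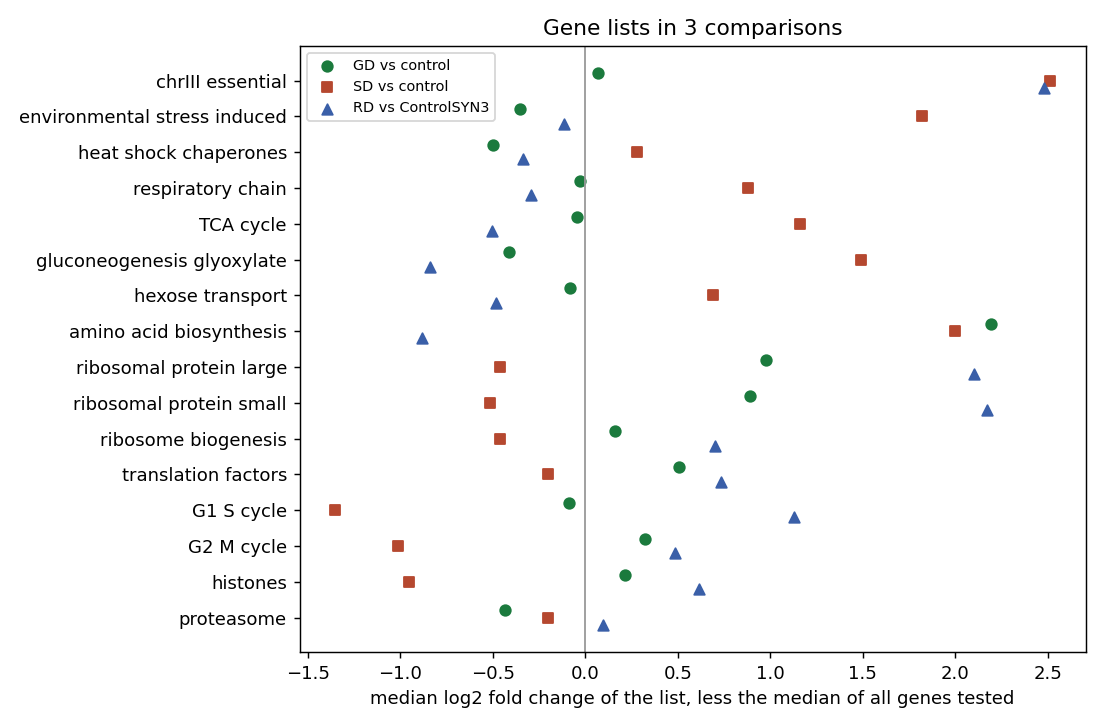
Median log2 fold change of 16 gene lists, less the median of all genes tested, in GD against control, SD against control and RD against ControlSYN3, with one symbol per comparison. Essential genes of chromosome III lay at 2.51 in SD and 2.48 in RD and at 0.07 in GD, and ribosomal protein genes lay above 0 in GD and RD and below 0 in SD.

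No single gene passed the test in RD against ControlSYN3, while the lists of chromosome III essential genes and ribosomal protein genes had the medians farthest above 0 among those described. The 13 essential genes had a median log2 fold change of 2.39, with 11 higher when adjusted over the list alone and none when adjusted over all genes (camera adjusted p = 7.36e-13, and adjusted p = 0.762 with an estimated correlation). Both arms of chromosome III, which hold these genes, passed the arm test as well (camera adjusted p = 1.63e-06 and 2.32e-06, and adjusted p = 0.999 with an estimated correlation). CDC39, a subunit gene of the Ccr4-Not complex (280117 to 286443), stood at 47.8, 58.3 and 65.6 FPKM in RD1, RD5 and RD6 and at 4.34 FPKM in ControlSYN3 (log2 fold change 3.44 ± 0.24, SE; limma adjusted p = 0.317). RRP43, although an essential gene, was listed at 0 in ControlSYN3, and stood at 76.9, 129 and 123 FPKM in RD1, RD5 and RD6. Large-subunit ribosomal protein genes had a median log2 fold change of 2.01 and small-subunit genes of 2.07, with none of 81 and none of 56 called, also when adjusted over the list alone (camera adjusted p = 5.45e-20 and 8.8e-17, and adjusted p = 0.762 with an estimated correlation for both). RD1 lay lower than the others. The large-subunit median was 0.871 in RD1, 2.46 in RD5 and 2.72 in RD6, and the small-subunit median was 0.909, 2.48 and 2.74.

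Of 19 genes of the G1/S transition, 16 were higher in RD when adjusted over the list alone and none when adjusted over all genes, with a median log2 fold change of 1.03 (camera adjusted p = 3.29e-14, and adjusted p = 0.762 with an estimated correlation).

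The limma test called 0 of 5895 genes, with 671 at an unadjusted p under 0.05 and a smallest adjusted p of 0.301. Leaving out RD1, whose mating-type genes differ from those of the other libraries, gave 3298 genes, 1346 higher and 1952 lower in RD5 and RD6, while leaving out RD5 or RD6 gave 0. The count without RD1 rests on the close agreement of RD5 and RD6 and on a single ControlSYN3 library. Without RD1, all 13 essential genes were higher, as were 80 of 81 large-subunit and 56 of 56 small-subunit ribosomal protein genes (camera adjusted p = 6.79e-11, 4.12e-33 and 1.22e-27, and adjusted p = 0.643 with an estimated correlation for all 3 lists). RPL9A stood at 833 and 1130 FPKM in RD5 and RD6, at 143 FPKM in RD1 and at 74.3 FPKM in ControlSYN3. Amino acid biosynthesis genes were lower in 36 of 49 cases and higher in 3, with 40 lower and 4 higher when adjusted over the list alone (camera adjusted p = 7.84e-07, and adjusted p = 0.643 with an estimated correlation). ARG1 stood at 285 and 194 FPKM in RD5 and RD6, at 3475 FPKM in RD1 and at 4915 FPKM in ControlSYN3. ARO9 and ARO10, of aromatic amino acid breakdown, stood at 40.5 and 27.4 FPKM in RD5 and at 1013 and 657 FPKM in ControlSYN3, with 586 and 445 FPKM in RD1. ZRT1 stood at 1498 to 2196 FPKM in the 3 RD libraries and at 52.5 FPKM in ControlSYN3. These genes of the fit without RD1 were chosen after their values were seen.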

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

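The tests of library scaling, of bins along chromosome II, of mixing, of a swap, of the lists of each gene's function and of shared reads were chosen after the results they bear on had been seen, while those of GC content, length and expression level and of other splits were set before. Against the control, 9 gene lists had medians on one side of 0 in all 3 GD libraries. In all 3 SD libraries their medians lay on the other side. GD and SD differed in 8 of these by camera with a preset correlation, and in none with an estimated one. Ergosterol synthesis was the exception (camera adjusted p = 0.0605). The lists were picked by the same values, so this count is no independent evidence of a difference. The medians of GD less SD were -2.28 for chromosome III essential genes, -2.22 for stress-induced genes, -1.42 for the tricarboxylic acid cycle, -1.32 for gluconeogenesis and the glyoxylate cycle, -1.12 for hexose transport and -1.02 for the respiratory chain. They were 1.40 for large-subunit and 1.44 for small-subunit ribosomal protein genes. The median of all genes lay at -0.44 in GD and -0.37 in SD, and less that median the GD values of the respiratory chain (-0.03), the tricarboxylic acid cycle (-0.05), hexose transport (-0.08) and the essential genes (0.07) lay near 0. The real split of the 6 GD and SD libraries called 2408 genes and the highest of the other splits called 0, so 1 of the 10 splits gave as many; 10 splits are too few for a share under 0.05.

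Chromosome II genes were higher in GD1 and GD3 than in GD2. Less the median of all other genes, chromosome II lay 0.236 above GD2 in GD1 and 0.514 in GD3, where the highest of 13 other chromosomes with at least 100 genes lay at 0.0378 and 0.0398; this argues against library scaling, which moves all chromosomes alike. After regression on GC content, coding length and expression level the values were 0.222 and 0.525, which argues against those as the whole cause. All 8 bins of 100 kb with at least 20 genes lay above 0 in both differences, from 0.193 to 0.285 in GD1 and from 0.391 to 0.761 in GD3, so a gain of the whole of chromosome II in those strains, or in part of their cells, is a candidate explanation, though the levels lay below the 1 on the log2 scale that a doubled chromosome would give. No biological explanation from the design was tested, and DNA copy number was not analysed here.

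RD1 had the mating-type expression of a-type cells. All 7 measured a-specific genes were higher in RD1 than in each of ControlSYN3, RD5 and RD6, and all 4 alpha-specific genes were lower, a pair of directions that scaling or depth does not give. The alpha-specific genes stood in RD1 at 0.465% to 6.32% of their lowest level in those libraries, which argues against a culture of mostly alpha cells with a-type cells mixed in. A swap with ControlSYN3 is argued against by the 13 of 13 essential genes of chromosome III that were higher in RD1, as in RD5 and RD6. A strain built in another parental background or a wrong label may each account for it, and no biological explanation was tested. The inferred match of MD and RD numbers decides only which strain name these values carry, as a column with them remains under any match.

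Essential gene rows of chromosome III were higher in SD than in GD and in the control, a wild-type library whose median of 36.3 FPKM lay between those of the GD libraries (30.7 to 39.2 FPKM). With median-of-ratios scaling the median of SD less GD was 2.25, with all 13 above 0, which argues against scaling. Of the 12 genes that another list also holds, 12 lay above the median of the other members of that list, by a median of 2.62, which argues against growth state as the whole cause: SPB1 lay at 3.37 in SD less GD, where the other ribosome biogenesis genes had a median of -0.588. Reads shared between wild-type and recoded copies remain open, since all 52 values in the control and GD lay above 0 and the tables do not mark copies; RRP43, an essential gene, was listed at 0 in ControlSYN3, so that a row need not hold the whole expression of its gene, unless that 0 is a failed estimate. The genotype difference between SD and GD, which the labels name without describing it, was not tested and stays open.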

How the results depend on the processing

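Median-of-ratios scaling and rescaling of each library to the same total were chosen after seeing the data; leaving out each strain library, RD1 included, was planned. Over 322 named gene and comparison pairs, 3452 of 3665 settings kept direction and side of the threshold, 130 lost the call, 83 gained it and 0 reversed; 74 of the gains came without RD1. Requiring a 2-fold change as well left 1144 genes for GD against control and 1083 for GD against SD, and 625 of the 1217 shared calls; fewer genes can pass by construction. Median-of-ratios scaling gave 690 shared calls, 377 higher and 313 lower, against 185 and 1032 without it. Not all of the 690 are therefore among the 1217. For GD against control, median-of-ratios scaling gave 1080 genes and the fit of only GD and control 233. The fit of only SD and control gave 3650 against 2468. The main fit used a common spread per gene for GD and SD. Pairs of GD libraries differed by more than 2-fold in 158 to 776 of 5648 rows, pairs of SD libraries in 20 to 126. Calls of GD against control thus rest partly on the smaller spread of SD, and calls of SD on the larger spread of GD. How much of these changes in count this accounts for was not tested. Leaving out single libraries gave 1176 to 2781 genes for GD against control, 1652 to 3257 for SD against control, 1263 to 3222 for GD against SD and 0 to 3298 for RD against ControlSYN3, where the fit without RD1 had fewer samples and a smaller spread. The lists past the test numbered 14 for GD against control, 16 for SD against control, 28 for GD against SD and 24 for RD against ControlSYN3. With an estimated correlation they numbered 0 in each comparison. Fry called 13, 13, 23 and 0 lists, not all of them past camera. It does not set a list against other genes, so its counts answer another question. For GD against SD the estimated correlation was 0.0411 for the essential genes and -0.0274 for oxidative stress genes, against the preset 0.01. Their camera adjusted p still rose from 5.96e-10 to 0.224 and from 0.0156 to 0.418. A high correlation between genes is therefore not needed for the loss. The estimated setting also rests on the residual degrees of freedom of the fit, 4 for GD, SD and control and 2 for RD and ControlSYN3. So few can alone raise the p-values, so the loss does not show that correlated genes caused it. The shares of the 2 were not tested. The arms past the test (1, 2, 2 and 2) likewise numbered 0 with an estimated correlation. For essential genes of chromosome III (medians 2.13, -2.28 and 2.39, which that correlation does not enter) the adjusted p was then 0.168, 0.224 and 0.762, under 0.05 in none. The numbers 1 to 3 in GD and SD do not pair the samples: deviations of same-numbered libraries correlated at -0.126, -0.18 and -0.166, and the replicate block fit called 1963 genes for GD against SD. No paired analysis was possible for the comparisons with wild-type libraries because each shares fewer than 2 numbers. The planned count tests, their normalization alternative and the joint fit were not run, since the tables hold no counts. The unknown depth leaves the precision of low values open.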

Other observations

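The list test without RD1 and the median-of-ratios scaling were chosen after seeing the data. Genes of metal uptake went both ways. Of 35 iron, copper and zinc genes, 5 were higher and 6 lower in GD against the control, 1 was higher and 8 lower in SD against the control, and 5 were higher and 2 lower in GD than in SD. When adjusted over the list alone these counts were 5 and 6, 1 and 7, and 4 and 0 (camera adjusted p = 0.486, 0.985 and 0.525), and with median-of-ratios scaling 7 were higher and 5 lower in SD against the control. Of 4 alpha-specific mating genes, 3 were higher in GD than in SD, also when adjusted over the list alone (camera adjusted p = 0.0426, adjusted p = 0.62 with an estimated correlation, and 0.0536 with median-of-ratios scaling). MF(ALPHA)2 stood at 1763, 386 and 1352 FPKM in GD1, GD2 and GD3 and at 127, 76.7 and 88.1 FPKM in SD1, SD2 and SD3. Without RD1, 47 of 65 mitochondrial ribosome genes were higher and 1 lower in RD than in ControlSYN3, with 47 and 1 when adjusted over the list alone (camera adjusted p = 2.59e-11, and adjusted p = 0.643 with an estimated correlation).

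Of 185 genes that the reference annotation places on chromosome III, 15 had a matched row in the table of GD, SD and control (8.11%), against 88.1% to 94.8% on the other nuclear chromosomes. That table holds 159 rows with short numbers that match no reference gene, and the other holds 158. Their median was 58.5 FPKM in the control, 37.0 to 45.1 FPKM in GD and 47.7 to 52.2 FPKM in SD, and they made up 2.50% to 2.93% of the FPKM in SD, 1.11% to 1.40% in GD, 1.44% in the control, 1.62% to 1.71% in RD and 2.03% in ControlSYN3. The row numbered 159 stood at 196, 90.6 and 139 FPKM in GD1, GD2 and GD3, at 7927, 6540 and 9396 FPKM in SD1, SD2 and SD3, and at 207 FPKM in the control. The row numbered 461 stood at 10.7 FPKM in GD1, was listed at 0 in GD2 and GD3, and stood at 564, 949.5 and 746 FPKM in SD1, SD2 and SD3 and at 75.7 FPKM in the control. In RD1, RD5 and RD6 row 159 stood at 1134, 796 and 586 FPKM, against 721 FPKM in ControlSYN3. Row 461 stood there at 984, 473 and 567 FPKM, against 21.4 FPKM.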
